A study of Mus musculus with 18 samples.

How the data were processed

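RNA-seq was done on quadriceps muscle and white adipose tissue of 9 mice, with 3 mice per regimen (vehicle, weekly and daily prednisone) and 18 libraries. Per the labels, RNA was extracted with Trizol and RNeasy columns and made into stranded mRNA libraries. The deposited table gives the authors' values as TPM, transcript abundances scaled to a fixed sum within each library, for 105129 Ensembl transcripts, with a gene symbol for each. Each library is a column of its own and all columns were used. Per the submitters' processing notes the reads were handled with Trimmomatic, HISAT2 and kallisto against mm10, with no version, role or order given, so the transcript annotation behind the values is not known. TPM keeps no read counts, so the depth of each library is unknown, and error was taken from the spread between mice.

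Transcript values were summed over each symbol to 33641 genes, of which 17279 had a single transcript. Genes with at least 1 TPM in at least 3 libraries of a tissue were tested, 12246 in muscle and 14150 in adipose tissue, as log2 of the TPM plus a pseudocount of 1. Among genes above this filter 47 shared all their values with another gene. Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 6 residual degrees of freedom, and p-values were adjusted with Benjamini-Hochberg over the genes of a comparison and called at 0.05. Log2 fold changes are given with the SE of limma and TPM with the SD of 3 libraries. The difference between tissues was tested with limma on each mouse's muscle minus adipose value, over 11737 genes. The labels state that both tissues came from each mouse, and libraries of a mouse were matched by the number in the labels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and positions are those of the mouse assembly GRCm38.

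The groups, comparisons, tests, most alternatives, 39 gene lists, a panel of 22 genes and the rule for naming genes were chosen before the data were examined. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), and camera with an estimated correlation and fry were run beside it: 35 lists in muscle and 36 in adipose tissue had enough members. With an estimated correlation 0 of the 13, 17 and 21 lists called in muscle after weekly, after daily and between the regimens still passed, and 1 of 16, 1 of 14 and 2 of 15 in adipose tissue. The genes named are the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap. Such genes also needed a mean of at least 5 TPM over the libraries of both groups compared. Also named are the panel, the 4 members with the smallest p of each passing list, and 5 genes in each direction for the difference between tissues. Predicted genes and segments of antigen receptors were not named. Some named genes are not reported here.

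Alternatives were TMM scaling (own code), quantile normalization, pseudocounts of 0.1 and 5, no filter or a filter at 5 TPM, a minimum log2 fold change of 1, array weights, a robust prior, transcripts in place of genes, both tissues in 1 fit, only the groups compared, a block for the replicate number, and each library left out. Leaving out a library of every group, leaving out adipose libraries with muscle transcripts, and a covariate for these were added after seeing the data. The numbers of the replicates do not pair mice across groups: residuals of the same number correlated at a median of -0.0304 in muscle and 0.0295 in adipose tissue. Residuals of the tissues of a mouse correlated at a median of 0.0464. With a block for the number 0, 1386 and 100 genes passed in muscle (weekly and daily against vehicle, weekly against daily) and 806, 0 and 12 in adipose tissue, by limma, where 1891 and 1305 genes had an unadjusted p under 0.05 without the block in the comparisons that gave 0.

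The tests were checked on simulated data. With 5 lists raised by 0.5 on the log2 scale for daily prednisone against vehicle, camera called all 5 as higher in each tissue. It also called 0 other lists as higher in muscle and 2 in adipose tissue. The simulated genes varied independently of each other, so this check cannot tell whether the preset correlation suits these data. With 200 changed genes at a log2 fold change of 1, limma found 96.5%, 95.5% and 96% of them in muscle and 91%, 89% and 88.5% in adipose tissue. These changed genes were drawn only from genes averaging above about 5 TPM. For the difference between tissues they were drawn from all genes tested, and 64% and 72% were found, so these shares cannot be set side by side. The simulated spread was that of the real replicates, so a spread that is too small would raise every share.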

Results

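RNA was sequenced from quadriceps muscle and white adipose tissue of obese male DBA/2J mice, an inbred strain, kept on a high-fat diet. Each of 9 mice gave both tissues, which made 18 libraries. In each tissue 3 libraries came from mice given vehicle, 3 from mice given prednisone once a week and 3 from mice given it every day, at 1 mg/kg by injection into the peritoneum for 12 weeks. Prednisone is a synthetic glucocorticoid, a steroid that acts through the glucocorticoid receptor. Tissue was taken 24 hours after the last injection. The labels give 3 daily libraries for adipose tissue and the table holds 3, although the design text of the series names fewer.

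The values are TPM, transcript abundances that the authors scaled to a fixed sum per library, summed per gene. TPM keeps no read counts, so the depth of each library is unknown and no counting interval can be given. Muscle libraries held 11781 to 12200 genes at 1 TPM or more and adipose libraries held 13413 to 14076. Genes encoded in the mitochondrial genome took 27.5% to 31.3% of the TPM in muscle and 12.9% to 16.9% in adipose tissue. Across genes, libraries of a group correlated at 0.984 to 0.992 in muscle and at 0.976 to 0.990 in adipose tissue, and libraries of different groups at 0.977 to 0.990 and 0.970 to 0.985.

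Both tissues held libraries with a feature that the groups do not explain. In every group the third library tended to lie between the first and the second. This was counted on the genes with the highest mean TPM, 3340 in muscle and 5653 in adipose tissue. The third library held the middle value for 43.6% to 58.6% of them, where equal shares would be 33.3%. If these libraries were not from separate mice, the spread between replicates would be too small and the p-values too low, so each count of changed genes is also given without the third library of each group. In adipose tissue, transcripts of skeletal muscle varied: Ckm, the creatine kinase of muscle, stood at 176, 130 and 109 TPM in weekly 2, weekly 3 and daily 2 and at 13.2 to 35 TPM in the others.

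**Figure D1:**
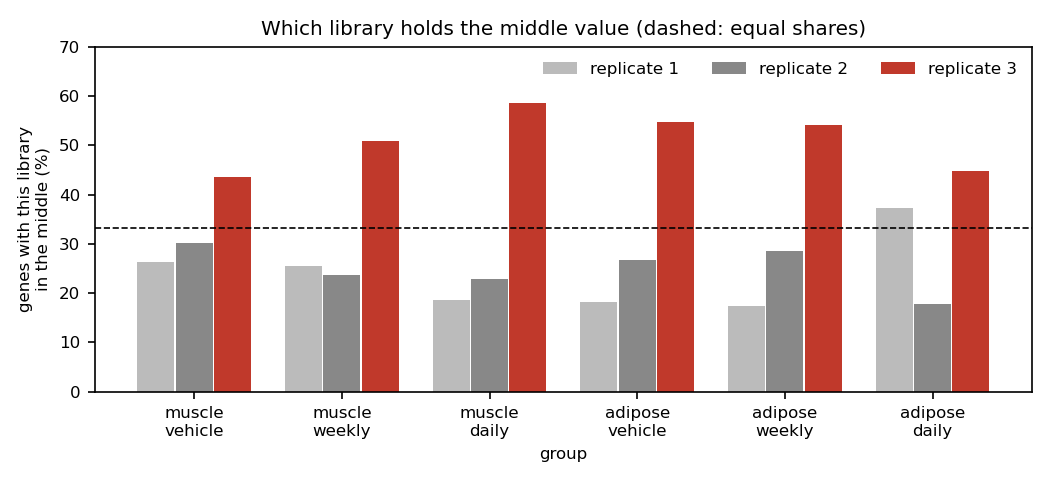
Percent of genes (vertical axis) for which replicate 1, 2 or 3 (bars) held the middle value, for each of the 6 groups of 3 libraries (horizontal axis). Only the genes with the highest mean TPM were counted, 3340 in muscle and 5653 in adipose tissue. The dashed line marks equal shares of 33.3%. Replicate 3 held the middle value most often in all 6 groups, from 43.6% in muscle of vehicle mice to 58.6% in muscle of daily mice.

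Daily prednisone against vehicle in muscle asked what the regimen given every day changed in that tissue. Genes of developing and regenerating muscle were among the largest rises. Myh3, the embryonic myosin heavy chain (chromosome 11, 67078300 to 67102291, GRCm38), rose by 3.82 ± 0.24 on the log2 scale (SE, n = 3 per group), from 0.656 ± 0.504 TPM (SD) to 22.2 ± 6.61 TPM, with an adjusted p of 0.000247 (limma, Benjamini-Hochberg). Tmem8c, which encodes the myoblast fusion protein myomaker, rose by 3.33 ± 0.24 to 16.8 ± 5.35 TPM, and Myog, a transcription factor of muscle differentiation (chromosome 1, 134289989 to 134292548), rose by 1.61 ± 0.12, from 8.07 ± 1.13 to 26.7 ± 4.4 TPM. Of 14 measured genes of denervation and regeneration 8 rose and 1, Hdac4, fell (adjusted p = 6.3e-10, or 0.138 with an estimated correlation). Adjusted over the list alone, 9 rose and 1 fell. Chrna1, a subunit of the acetylcholine receptor of the muscle endplate, rose by 0.96 ± 0.11, from 4.17 ± 0.222 to 9.11 ± 0.899 TPM, and Myh8, the perinatal myosin, rose by 1.57 ± 0.17.

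Some genes of the slow fibre list and some macrophage markers also rose after daily prednisone in muscle. Of 15 slow fibre genes 6 rose (adjusted p = 1.04e-06, or 0.185 with an estimated correlation), and adjusted over the list alone 6 rose and 1 fell. The mature slow genes Myl2 and Myl3, light chains of slow myosin, were not called, with log2 fold changes of 0.07 and 0.25, and Myh7, the slow myosin heavy chain, lay below the filter and was at -0.03 when added. Among those that rose Tnni1, the slow troponin I (chromosome 1, 135779434 to 135810989), rose by 2.87 ± 0.18, from 2.76 ± 0.681 to 26.8 ± 6.89 TPM. Tnnt2, the cardiac troponin T also found in immature muscle, rose by 2.72 ± 0.18, and Myl4, a myosin light chain of embryonic muscle and atrium, rose by 2.79 ± 0.30. Of 25 macrophage markers 10 rose, and 13 adjusted over the list alone (adjusted p = 6.21e-14, or 0.278 with an estimated correlation). Ctss, a lysosomal protease of macrophages, rose by 1.75 ± 0.19, from 13.9 ± 2.48 to 50 ± 14.7 TPM, and Lyz2, lysozyme, rose by 1.16 ± 0.14, from 118 ± 22.6 to 266 ± 45.3 TPM. Spp1, which encodes the secreted protein osteopontin (chromosome 5, 104435118 to 104441050), rose by 2.95 ± 0.18 to 21.9 ± 5.34 TPM. Of 30 matrix genes 5 rose (adjusted p = 7.82e-09, or 0.403 with an estimated correlation), 8 adjusted over the list alone, and Postn, the matrix protein periostin, rose by 2.20 ± 0.26, from 6.22 ± 1.15 to 33.4 ± 13.1 TPM. Of 10 proliferation genes 4 rose (adjusted p = 6.78e-06, or 0.185 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 0.379 ± 0.099 to 1.54 ± 0.306 TPM.

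Lists of energy metabolism passed as lower in muscle after daily prednisone. Of 53 genes of oxidative phosphorylation 30 fell and 1, Cycs, rose (adjusted p = 9.61e-11, or 0.105 with an estimated correlation). Adjusted over the list alone, 41 fell and 3 rose. Atp5a1, a subunit of ATP synthase, fell by 0.39 ± 0.04. Of 18 genes of the tricarboxylic acid cycle 15 fell, also adjusted over the list alone (adjusted p = 2.03e-09, or 0.151 with an estimated correlation). Of 26 genes of fatty acid oxidation 15 fell, 21 adjusted over the list alone (adjusted p = 2.84e-07, or 0.212 with an estimated correlation). Hadha, which carries steps of mitochondrial beta oxidation, fell by 0.45 ± 0.05, from 232 ± 14.2 to 169 ± 3.07 TPM. Of 22 genes of branched-chain amino acid breakdown 12 fell, 16 adjusted over the list alone (adjusted p = 3.42e-05, or 0.212 with an estimated correlation). Of 27 genes of glycolysis and glycogen 10 fell, 12 adjusted over the list alone (adjusted p = 0.00226, or 0.321 with an estimated correlation), among them Gys1, the glycogen synthase of muscle, which fell by 0.56 ± 0.07.

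Among genes known to answer to glucocorticoids in muscle, Trim63, the ubiquitin ligase MuRF1, rose by 0.47 ± 0.05, from 138 ± 6.05 to 192 ± 10.6 TPM (adjusted p = 0.0021). In the panel Fbxo32 was not called by limma (0.14 ± 0.15, adjusted p = 0.573), nor were Klf15, Zbtb16, Tsc22d3, Per1 and Pdk4 (0.146 to 0.862). Nr3c1, the receptor itself, fell by 0.26 ± 0.07 (0.0478, or 0.383 without the third library of each group). Fbxo31, another part of a ubiquitin ligase, from the atrophy list, fell by 0.59 ± 0.06. Of 29 genes of the atrophy program 1 rose and 9 fell (adjusted p = 0.0265, or 0.403 with an estimated correlation); adjusted over the list alone, 1 rose and 15 fell. The call of this list was lost without daily 1 (adjusted p = 0.0642) or vehicle 2 (0.0733) and under TMM scaling (0.105). Fkbp5, a co-chaperone of the receptor, rose by 0.49 ± 0.12 and Mt2, a metallothionein, by 1.24 ± 0.25, from 15 ± 3.21 to 37.9 ± 14.4 TPM. The call of Mt2 was lost without daily 3 (adjusted p = 0.0608), and that of Fkbp5 without daily 3 (0.0733), vehicle 1 (0.0782), vehicle 2 (0.0722) or vehicle 3 (0.0742). Of 27 glucocorticoid receptor targets 3 rose and 4 fell, and the list did not pass (adjusted p = 0.172). Socs2, a brake on cytokine and growth hormone signalling, fell by 1.27 ± 0.20, from 12.5 ± 3.63 to 4.44 ± 0.384 TPM. Slc2a4, the insulin-responsive glucose transporter, fell by 0.33 ± 0.06 (adjusted p = 0.011), a call lost without daily 3 (0.054) and under TMM scaling (0.063).

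Smaller lists passed in the same comparison. Of 20 interferon response genes 4 rose (adjusted p = 1.93e-06, or 0.0525 with an estimated correlation), 8 adjusted over the list alone. Of 19 genes of the unfolded protein response 3 rose (adjusted p = 0.00864, or 0.213 with an estimated correlation), and Hsp90b1, a chaperone of the endoplasmic reticulum, rose by 0.33 ± 0.05. Of 20 immediate early genes 2, Junb and Myc, rose (adjusted p = 0.0183, or 0.403 with an estimated correlation), although the median (-0.02) and the mean (-0.01) of the list lay below 0, and the call was lost without vehicle 1 (0.245) and under TMM scaling (0.0771), where the median lay at 0.07. The call of Myc itself was lost without daily 3 (0.0607). Inflammatory cytokines passed as higher (adjusted p = 0.0116, or 0.403 with an estimated correlation) with 0 of 12 members called by limma, and the call was lost without daily 1 (0.0981) or vehicle 1 (0.0568) and under TMM scaling (0.0625). Markers of fibro-adipogenic progenitors passed as higher (adjusted p = 0.0116, or 0.548 with an estimated correlation), lost without daily 1 (0.192) or vehicle 1 (0.186). Lipolysis genes passed as lower with 3 of 12 called (adjusted p = 0.0479, or 0.575 with an estimated correlation), lost without daily 2 (0.214), vehicle 1 (0.107) or vehicle 3 (0.079).

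Limma called 1674 of 12246 genes in muscle after daily prednisone, 234 higher and 1440 lower, which is 86.0% lower. Under TMM scaling, which sets the bulk of genes to the same level, it called 822, 374 higher and 448 lower, with 678 called under both scalings, and the median log2 fold change of all genes moved from -0.09 to -0.00. Members that fell were then 14 of the 53 genes of oxidative phosphorylation, 7 of the 18 of the tricarboxylic acid cycle and 7 of the 26 of fatty acid oxidation. Leaving out a library gave 961 genes without vehicle 1, 878 without vehicle 2 and 532 without daily 3. Of 73 named calls 47 were kept without each single library. Without the third library of each group 8 genes passed (1967 at an unadjusted p under 0.05): Myh3, Spp1, Tnni1 and Tnnt2 were called with an adjusted p of 0.0468, and Tmem8c and Myog reached 0.0629. Rps12l1 was listed at 0 TPM in the vehicle libraries and is uncertain, as are mt-Nd3, mt-Co2 and Eif1-ps1, since these genes share reads with close copies.

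**Figure D2:**
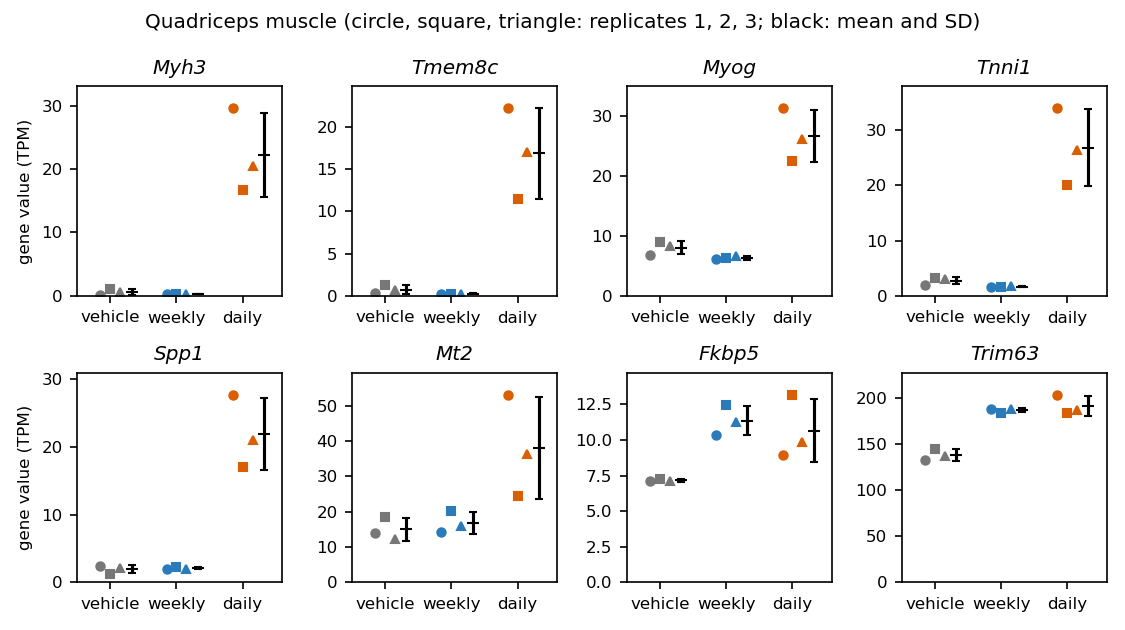
Gene values in TPM (vertical axes) of 8 genes in quadriceps muscle after vehicle, weekly or daily prednisone (horizontal axes), with a point per library and the mean and SD of 3 libraries in black. The 3 daily libraries stood above all vehicle and weekly libraries for Myh3, Tmem8c, Myog, Tnni1 and Spp1, while Trim63 averaged 187 TPM after weekly and 192 TPM after daily prednisone against 138 TPM after vehicle.

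Weekly prednisone against vehicle in muscle asked what the same dose given once a week changed. Nfil3, a transcription repressor tied to the circadian clock (chromosome 13, 52967209 to 52981073), rose by 0.57 ± 0.07, from 21.9 ± 0.156 to 33.1 ± 0.725 TPM (adjusted p = 0.0234). Trim63 rose by 0.43 ± 0.05, from 138 ± 6.05 to 187 ± 2.26 TPM (adjusted p = 0.0287). Mafa, a transcription factor of the Maf family, fell by 0.52 ± 0.06, from 50.3 ± 2.01 to 34.7 ± 1.21 TPM (adjusted p = 0.0234). Cyp26b1, which breaks down retinoic acid, rose by 1.34 ± 0.14 and Irgm2, an interferon-inducible GTPase, fell by 0.65 ± 0.07; both, like Rps13-ps1, whose value is uncertain since it shares reads with its parent gene, were named after their values were seen. The genes of regeneration that rose after daily prednisone were not called here, and Myh3 stood at 0.309 ± 0.0244 TPM.

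Among lists, 20 interferon response genes passed as higher in muscle after weekly prednisone, with a median of 0.13 (adjusted p = 3.08e-05, or 0.0662 with an estimated correlation), and 38 ribosomal protein genes passed as lower, with a median of -0.16 (adjusted p = 3.08e-05, or 0.767 with an estimated correlation). Oxidative phosphorylation passed as lower, with a median of -0.08 (adjusted p = 3.08e-05, or 0.457 with an estimated correlation), lost under TMM scaling (0.312), and glycolysis passed as lower with a median of -0.13 (adjusted p = 0.000896, or 0.457 with an estimated correlation). By limma no member of these lists was called over all genes. Adjusted over the list alone, 1 gene of oxidative phosphorylation rose and 15 fell, and 7 genes fell both in glycolysis and among ribosomal proteins. The 27 glucocorticoid receptor targets passed as higher (adjusted p = 0.0179, or 0.457 with an estimated correlation) with a mean of 0.05 and a median of -0.00, and the call was lost without weekly 2 (0.363). Fkbp5 stood at 7.17 ± 0.105 TPM after vehicle and 11.4 ± 1.04 TPM after weekly prednisone. Its log2 fold change of 0.59 ± 0.12 was not called by limma (adjusted p = 0.123). After daily prednisone it was 0.49 ± 0.12, and the difference between the regimens was not called (0.10 ± 0.12, adjusted p = 0.741). Genes encoded in the mitochondrial genome passed as higher (adjusted p = 3.08e-05, or 0.457 with an estimated correlation), with a median of 0.09 and a mean of -0.02, and share reads with nuclear copies. Lower as well were the tricarboxylic acid cycle (adjusted p = 0.00398, or 0.592 with an estimated correlation), branched-chain amino acid breakdown (adjusted p = 0.00398, or 0.552 with an estimated correlation) and fast fibre genes (adjusted p = 0.0223, or 0.79 with an estimated correlation). Higher were cholesterol synthesis (adjusted p = 0.00479, or 0.607 with an estimated correlation), progenitor markers (adjusted p = 0.0103, or 0.79 with an estimated correlation), the unfolded protein response (adjusted p = 0.0223, or 0.457 with an estimated correlation) and lipogenesis (adjusted p = 0.0459, or 0.79 with an estimated correlation). TMM scaling ended the calls of the tricarboxylic acid cycle (0.581), fast fibre genes (0.308) and lipogenesis (0.101), and leaving out vehicle 1 those of the unfolded protein response (0.0527), progenitor markers (0.376) and fast fibre genes (0.271). The calls of cholesterol synthesis, progenitor markers, fast fibre genes and lipogenesis were lost without weekly 2 (0.0991, 0.0905, 0.0977 and 0.206), that of the unfolded protein response without weekly 1 (0.129), that of fast fibre genes without vehicle 3 (0.0604) and that of lipogenesis without vehicle 2 (0.23) or weekly 3 (0.0526).

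The lists called in muscle after weekly prednisone fell from 13 to 9 without the third library of each group. By limma 6 of 12246 genes passed in muscle after weekly prednisone, 4 higher and 2 lower, and 8 passed under TMM scaling. The median log2 fold change of all genes was -0.07, and -0.01 under TMM scaling. Leaving out a single library left 0 genes without vehicle 1, vehicle 3 or weekly 2 and 1 gene without vehicle 2, weekly 1 or weekly 3, and 0 passed without the third library of each group, against 1891 genes at an unadjusted p under 0.05 with all libraries and 805 without the third. The adjusted p of Nfil3 reached 0.163 without vehicle 1, 0.126 without vehicle 2, 0.0725 without vehicle 3, 0.122 without weekly 1, 0.0905 without weekly 2 and 0.176 without weekly 3. That of Trim63 reached at most 0.205 and that of Mafa at most 0.176, both without weekly 3.

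Weekly against daily prednisone in muscle asked how the regimens differed from each other. Some genes of regeneration and immature muscle were lower after weekly than after daily prednisone: Myh3 differed by -4.11 ± 0.24 (adjusted p = 0.000105), Tmem8c by -3.78 ± 0.24, and Actc1, the cardiac actin found in immature muscle, by -2.87 ± 0.18, with 6.3 ± 0.401 TPM after weekly and 54 ± 16.3 TPM after daily prednisone. Of 14 regeneration genes 6 were lower (adjusted p = 1.41e-11, or 0.113 with an estimated correlation), and 10 were lower and 1 higher adjusted over the list alone. Of 25 macrophage markers 9 were lower, 15 adjusted over the list alone (adjusted p = 2.68e-18, or 0.202 with an estimated correlation), and Ctss stood at 10.7 ± 0.429 TPM after weekly prednisone. Hr, a corepressor of nuclear receptors (chromosome 14, 70552212 to 70573548), was higher by 0.72 ± 0.09, with 24.8 ± 1.95 against 14.7 ± 1.45 TPM (adjusted p = 0.00536), and Nfil3 was higher by 0.59 ± 0.07 (adjusted p = 0.00354).

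Lists of energy metabolism passed as higher in muscle after weekly than after daily prednisone, with a minority of their members called. Of 26 genes of fatty acid oxidation 7 were higher (adjusted p = 1.41e-11, or 0.113 with an estimated correlation), and 18 were higher and 1 lower adjusted over the list alone. In the tricarboxylic acid cycle 4 of 18 genes were higher, 16 adjusted over the list alone (adjusted p = 2.92e-10, or 0.113 with an estimated correlation). In oxidative phosphorylation 4 of 53 genes were higher, 22 adjusted over the list alone (adjusted p = 8.82e-10, or 0.113 with an estimated correlation). Slow fibre genes were lower with 5 called (adjusted p = 9.61e-07, or 0.189 with an estimated correlation), matrix genes with 4 called (adjusted p = 8.82e-10, or 0.418 with an estimated correlation) and proliferation genes with 3 called (adjusted p = 3.73e-08, or 0.113 with an estimated correlation). Branched-chain amino acid breakdown (adjusted p = 0.00103), mast cell markers (0.00911), endothelial markers (0.0129), lipogenesis (0.0167), clock genes (0.0173), the atrophy program (0.0173), triglyceride storage (0.0339) and thermogenic genes (0.038) also passed as higher after weekly prednisone. Ribosomal proteins (9.61e-07), immediate early genes (0.000746), inflammatory cytokines (0.00354), fast fibre genes (0.00354) and interferon response genes (0.035) passed as lower. With an estimated correlation the adjusted p of these lists was 0.194 to 0.438, and without daily 2 the calls of mast cell markers (0.0622), endothelial markers (0.0809), fast fibre genes (0.0809), interferon response genes (0.0809), lipogenesis (0.297), thermogenic genes (0.323) and triglyceride storage (0.429) were lost. Without weekly 2 those of lipogenesis (0.0894), thermogenic genes (0.0894), triglyceride storage (0.0934) and interferon response genes (0.0502) were lost, the last also without weekly 1 (0.0797) or daily 3 (0.0736) and under TMM scaling (0.0613), and that of thermogenic genes without weekly 3 (0.0514). Adipocyte markers summed to 3465, 1505 and 2223 TPM in daily 1, 2 and 3 of muscle. In weekly 1, 2 and 3 they summed to 2509, 3076 and 2749 TPM. Whether fat in the samples accounts for the calls of lipogenesis, thermogenic genes and triglyceride storage was not tested. Limma called 217 genes, 112 higher and 105 lower after weekly prednisone, and TMM scaling gave 203, 73 higher and 130 lower. Of 53 named calls 18 were kept without each single library. The count was 64, 99 and 53 without weekly 1, 2 and 3, 125 without daily 1 and 37 without daily 3, and 10 passed without the third library of each group, 8 of them among the 217.

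Weekly prednisone against vehicle in adipose tissue asked what dosing once a week changed there. Thbs1, the matrix glycoprotein thrombospondin 1 (chromosome 2, 118111876 to 118127133), rose by 1.54 ± 0.07, from 34.8 ± 0.882 to 103 ± 6.16 TPM (adjusted p = 2.06e-05). Cd163, the haemoglobin scavenger receptor of macrophages (chromosome 6, 124304656 to 124330527), rose by 1.19 ± 0.11, from 12.6 ± 1.63 to 29.9 ± 2.43 TPM. Rnase2a, a secreted ribonuclease (chromosome 14, 51255262 to 51256112), rose by 2.02 ± 0.26, from 23.8 ± 6.29 to 101 ± 33.3 TPM, and Tmem100, a membrane protein of endothelium, rose by 1.43 ± 0.12. Fn1, fibronectin, rose by 1.08 ± 0.11, from 133 ± 9.8 to 284 ± 40.7 TPM.

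Lists of stromal and vessel genes passed as higher in adipose tissue after weekly prednisone, with part of their members called. Of 30 matrix genes 13 rose, 20 adjusted over the list alone (adjusted p = 3.05e-07, or 0.509 with an estimated correlation), and under TMM scaling 8 rose. Of 15 markers of fibro-adipogenic progenitors 10 rose, 11 adjusted over the list alone (adjusted p = 1.85e-05, or 0.356 with an estimated correlation), and under TMM scaling 7 rose. Cd34, a marker of stromal progenitors and endothelium, rose by 0.63 ± 0.08, from 76.8 ± 4.09 to 119 ± 9.03 TPM, Clec3b, tetranectin, by 0.57 ± 0.06 and Thy1 by 0.71 ± 0.10. Of 18 endothelial markers 6 rose, 11 adjusted over the list alone (adjusted p = 0.000911, or 0.651 with an estimated correlation). Of 28 macrophage markers 5 rose, 13 adjusted over the list alone (adjusted p = 0.00111, or 0.651 with an estimated correlation), a list call lost without vehicle 2 (0.0918). Of 15 markers of mesothelium, the lining of the fat depot, 5 rose, 10 adjusted over the list alone (adjusted p = 0.00237, or 0.651 with an estimated correlation), lost without weekly 2 (0.0928). Fast muscle fibre genes passed as higher with a median of 1.72 (adjusted p = 0.00237, or 0.707 with an estimated correlation), lost without weekly 2 (0.186), and Ckm read 13.8, 176 and 130 TPM in the weekly libraries. Msln, a mesothelial gene, stood at 34.5 and 29.5 TPM in weekly 2 and weekly 3 and at 12.1 to 23.3 TPM in the other adipose libraries, so these libraries also stood highest for mesothelium.

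Lists of mitochondrial genes and of adipocyte markers passed as lower in adipose tissue after weekly prednisone, with a minority of their members called. Of 53 genes of oxidative phosphorylation 10 fell, and adjusted over the list alone 34 fell and 1 rose (adjusted p = 9.17e-26, or 0.356 with an estimated correlation). Of 26 genes of fatty acid oxidation 3 fell, 8 adjusted over the list alone (adjusted p = 1.48e-08, or 0.05, just under the threshold, with an estimated correlation). Of 18 genes of the tricarboxylic acid cycle 2 fell (adjusted p = 1.44e-09, or 0.284 with an estimated correlation), of 38 ribosomal protein genes 3 fell and 1 rose (adjusted p = 7.05e-12, or 0.356 with an estimated correlation), and of 22 adipocyte markers 3 fell and 1 rose (adjusted p = 0.000159, or 0.436 with an estimated correlation). Of 22 genes of branched-chain amino acid breakdown 2 fell (adjusted p = 5.91e-06, or 0.356 with an estimated correlation), and of 16 genes of triglyceride storage 1, Cidea, fell (adjusted p = 0.00198, or 0.356 with an estimated correlation). Of 22 immediate early genes 4 rose (adjusted p = 0.0108, or 0.356 with an estimated correlation). Lymphocyte markers (adjusted p = 0.00973, or 0.436 with an estimated correlation) and thermogenic genes (adjusted p = 0.0149, or 0.356 with an estimated correlation) passed as lower with 1 member called in each, lost under TMM scaling (0.118 and 0.154) and without vehicle 1 (0.121) for lymphocytes and vehicle 3 (0.0588) for thermogenic genes. Adipoq, which encodes adiponectin, did not pass, with log2 fold changes of 0.05 after weekly (adjusted p = 0.749) and -0.08 after daily prednisone (adjusted p = 0.809), nor did Lep, which encodes leptin, after weekly prednisone (adjusted p = 0.991). Lars2, the mitochondrial leucyl-tRNA synthetase, fell by 1.16 ± 0.21, from 449 ± 8.12 to 200 ± 5.36 TPM, lost without vehicle 3 (0.0733) or weekly 3 (0.0703), and its value is uncertain. Fkbp5 rose by 0.45 ± 0.09, from 11.6 ± 0.711 to 16.1 ± 1.01 TPM (adjusted p = 0.0232), lost without vehicle 1 (0.0509), vehicle 3 (0.0849) or weekly 3 (0.0896) and under TMM scaling (0.053).

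Limma called 1052 of 14150 genes in adipose tissue after weekly prednisone, 809 higher and 243 lower. TMM scaling gave 1032, with 493 higher and 539 lower, 725 called under both scalings, and moved the median log2 fold change of all genes from 0.13 to 0.02, so changes of a given gene are relative to that shift. The count was 405, 360 and 64 without vehicle 1, 2 and 3, and 361 and 66 without weekly 1 and weekly 3. Of 60 named calls 9 were kept without each single library, among them Thbs1, Tmem100, Cd163, Fn1, Clec3b, Cd34, Thy1 and Rnase2a. Without the third library of each group Thbs1 alone passed (adjusted p = 0.0259), with 1941 genes at an unadjusted p under 0.05. Without weekly 2, weekly 3 and daily 2, the libraries with the most muscle transcripts, 2145 genes passed, 712 of them among the 1052; the lone weekly library is then assumed to vary like the other groups. With the level of muscle genes as a covariate 4130 passed.

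**Figure D3:**
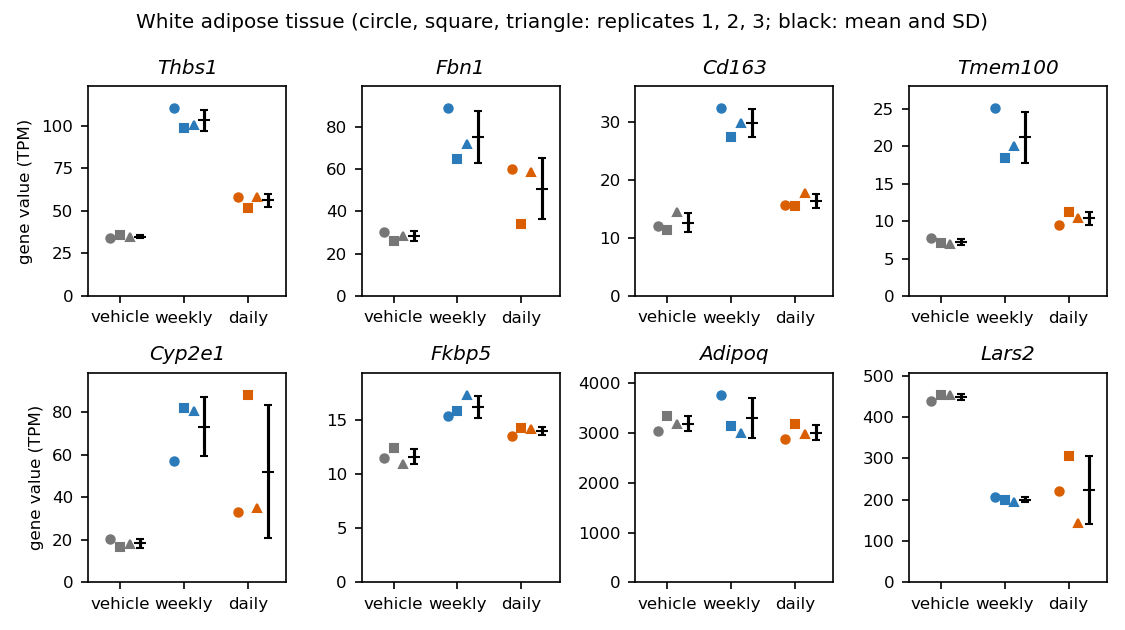
Gene values in TPM (vertical axes) of 8 genes in white adipose tissue after vehicle, weekly or daily prednisone (horizontal axes), with a point per library and the mean and SD of 3 libraries in black. Thbs1 averaged 34.8 TPM after vehicle, 103 TPM after weekly and 56.1 TPM after daily prednisone, and the 3 groups did not overlap. The largest changes were named only among genes whose groups did not overlap, so this adds no support. By chance 3 separate libraries per group show it in 10% of comparisons of a pair of groups. Over all adipose genes tested it held for 35.45% (weekly against vehicle), 15.59% (daily against vehicle) and 25.53% (weekly against daily).

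Daily prednisone against vehicle in adipose tissue asked what dosing every day changed there. Thbs1 rose by 0.67 ± 0.07, from 34.8 ± 0.882 to 56.1 ± 3.77 TPM (adjusted p = 0.0498), and no other gene passed. Of 28 macrophage markers 0 were called over all genes by limma and 7 rose adjusted over the list alone, and the list passed as higher with a median of 0.22 (adjusted p = 2.81e-08, or 0.686 with an estimated correlation). Oxidative phosphorylation passed as lower with a median of -0.13 (adjusted p = 5.15e-13, or 0.686 with an estimated correlation). Genes encoded in the mitochondrial genome passed as higher with a median of 0.27 (adjusted p = 1.27e-11, or 0.0451 with an estimated correlation), with 10 higher adjusted over the list alone, and these genes share reads with nuclear copies. Matrix genes passed as higher (adjusted p = 0.00157, or 0.765 with an estimated correlation) with 4 members adjusted over the list alone, and adipocyte markers passed as lower (adjusted p = 0.00232, or 0.765 with an estimated correlation), lost without vehicle 2 (0.0773). Fast muscle fibre genes passed as higher (adjusted p = 0.0211, or 0.84 with an estimated correlation), lost without vehicle 2 (0.312), vehicle 3 (0.0609) or daily 2 (0.43) and under TMM scaling (0.0536). The tricarboxylic acid cycle (adjusted p = 0.00017, or 0.627 with an estimated correlation) and branched-chain amino acid breakdown (adjusted p = 0.00109, or 0.729 with an estimated correlation) passed as lower and progenitor markers as higher (adjusted p = 0.0126, or 0.765 with an estimated correlation). Ribosomal proteins (0.00231), erythrocyte transcripts (0.0113), proliferation (0.00381), lipogenesis (0.0346) and fatty acid oxidation (0.042) passed with all libraries but each lost its call without at least 1 of them, at up to 0.888, 0.888, 0.0865, 0.323 and 0.34 (the direction of ribosomal proteins turned without vehicle 1, and that of the fast fibre genes without daily 2), and at 0.765, 0.765, 0.765, 0.765 and 0.627 with an estimated correlation. TMM scaling also ended the call of fatty acid oxidation (0.116). The calls lost without the third library of each group were those of fatty acid oxidation (0.312), adipocyte markers (0.136), matrix genes (0.0865), progenitor markers (0.0776), erythrocyte transcripts (0.0609) and proliferation (0.0567).

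By limma 1 of 14150 genes passed in adipose tissue after daily prednisone, against 1305 at an unadjusted p under 0.05. The adjusted p of Thbs1 was 0.178 without daily 1, 0.375 without daily 3, 0.143 without vehicle 2 and 0.118 without vehicle 3. The count was 14 without vehicle 1, 2 without vehicle 3, 3 without daily 2 and 0 without daily 1 or daily 3. Without the third library of each group 0 genes passed, with 399 at an unadjusted p under 0.05.

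Weekly against daily prednisone in adipose tissue asked how the regimens differed there. Tppp3, a tubulin-binding protein (chromosome 8, 105467493 to 105471526), was higher after weekly prednisone by 1.32 ± 0.12, with 188 ± 9.79 against 74.8 ± 9.69 TPM (adjusted p = 0.00378). Thbs1 was higher by 0.87 ± 0.07 (adjusted p = 0.00378). Lyve1, a receptor for hyaluronan on lymphatic endothelium and on some macrophages (chromosome 7, 110850607 to 110863239), was higher by 1.01 ± 0.13, with 19.7 ± 2.97 against 9.26 ± 0.522 TPM, and its call was lost without daily 1 (0.0879), daily 3 (0.0992), weekly 1 (0.0557) or weekly 3 (0.13). Elovl3, a fatty acid elongase (chromosome 19, 46131897 to 46135694), was lower by -0.94 ± 0.13, with 3.71 ± 0.328 against 8 ± 0.536 TPM (adjusted p = 0.0265), a call lost whichever single library was left out (0.13, 0.11, 0.0883, 0.113, 0.0671 and 0.0644 without weekly 3, daily 1, daily 2, daily 3, weekly 1 and weekly 2).

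In the same comparison, 15 markers of mesothelium passed as higher after weekly prednisone (adjusted p = 1.72e-07, or 0.358 with an estimated correlation), 11 adjusted over the list alone. Endothelial markers passed as higher (adjusted p = 1.79e-06, or 0.442 with an estimated correlation), 13 adjusted over the list alone, as did matrix genes with 4 called (adjusted p = 1.79e-06, or 0.55 with an estimated correlation). Fatty acid oxidation (adjusted p = 6.09e-10, or 0.0278 with an estimated correlation), oxidative phosphorylation (adjusted p = 3.33e-15, or 0.355 with an estimated correlation) and genes encoded in the mitochondrial genome (adjusted p = 6.57e-11, or 0.0278 with an estimated correlation) passed as lower. Proliferation genes passed as lower (adjusted p = 0.0148, or 0.766 with an estimated correlation) although their median (0.02) and mean (0.01) lay above 0, and the call was lost without daily 3 (0.124) or weekly 2 (0.517) and under TMM scaling (0.0744), where the median lay at -0.08. Ribosomal proteins (adjusted p = 5.17e-11), the tricarboxylic acid cycle (1.77e-06), triglyceride storage (7.4e-06), lymphocyte markers (5.96e-05), thermogenic genes (0.000726) and branched-chain amino acid breakdown (0.00225) also passed as lower, and progenitor markers (4.56e-06) and immediate early genes (0.0261) as higher, with adjusted p of 0.168 to 0.537 with an estimated correlation. The call of branched-chain amino acid breakdown was lost without weekly 1 (0.493), and that of immediate early genes without daily 1 (0.0737), daily 3 (0.285), weekly 2 (0.0684) or weekly 3 (0.0531). Limma called 44 genes, 42 higher and 2 lower, and 14 under TMM scaling, 11 higher and 3 lower, where the median of all genes moved from 0.12 to 0.00. The count was 17, 24 and 2 without weekly 1, 2 and 3 and 2 without daily 1 or daily 3. Without the third library of each group 0 passed, with 859 at an unadjusted p under 0.05. Without weekly 2, weekly 3 and daily 2 it was 2, and with the level of muscle genes as a covariate 1794.

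**Figure D4:**
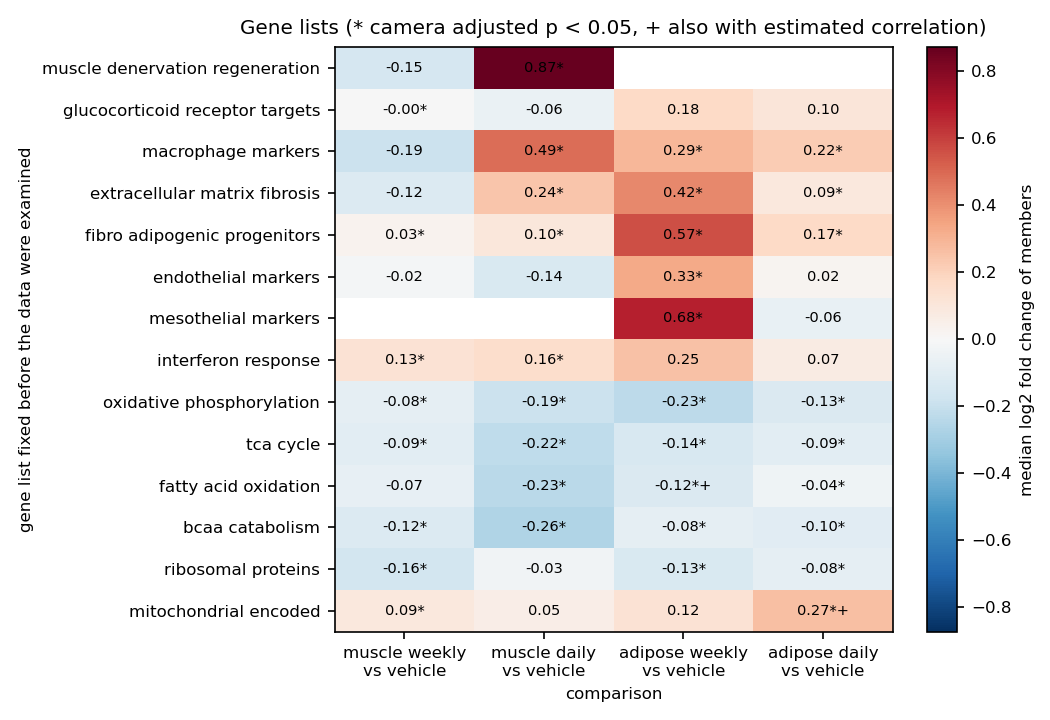
Median log2 fold change (colour and number) of the members of 14 gene lists (vertical axis) in 4 comparisons against vehicle (horizontal axis), with a star for an adjusted p under 0.05 by camera and a plus for one that also passed with an estimated correlation; white cells are lists with fewer than 5 tested members, which were not tested. Regeneration genes had a median of 0.87 in muscle after daily prednisone, and oxidative phosphorylation was below 0 in all 4 comparisons. In muscle after weekly prednisone the median of all genes was itself at -0.07, and the call of oxidative phosphorylation was lost under TMM scaling.

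The effects of the weekly and the daily regimen in a tissue were compared gene by gene. Both are measured against the same 3 vehicle libraries, which alone makes them correlate. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.495 in muscle and 0.659 in adipose tissue, where simulated unchanged groups gave 0.496 and 0.5. Their covariance was 0.02745 in muscle and 0.05298 in adipose tissue, against 0.01442 and 0.02462 simulated, a difference that was not tested. The direction was shared by 73.4% of genes in muscle and 72.3% in adipose tissue, against 66.7% and 66.6% simulated. Trim63 was the gene higher in both comparisons in muscle, and Thbs1 was the one in adipose tissue. In muscle 2 genes, Mafa and Irgm2, were lower in both. Whether these counts exceed what the shared vehicle libraries give was not tested.

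The difference between muscle and adipose tissue asked whether a regimen acted unequally on the tissues of the same mouse. After weekly prednisone Thbs1 rose in adipose tissue (1.54) and was at 0.14 in muscle, a difference of -1.40 ± 0.16 (adjusted p = 0.0201). Tmem100, at 1.43 in adipose tissue and 0.14 in muscle, differed by -1.29 ± 0.19 (adjusted p = 0.0292), and Fbn1, the matrix protein fibrillin 1, by -1.48 ± 0.22 (adjusted p = 0.0302). After daily prednisone Spp1, at 2.95 in muscle and 0.11 in adipose tissue, differed by 2.84 ± 0.34 (adjusted p = 0.0441), and Tubb2b, a beta tubulin, by 1.27 ± 0.13 (adjusted p = 0.0201). Limma on the difference within each mouse called 326 of 11737 genes for the weekly regimen, 7 with the muscle effect above and 319 with it below the adipose effect, and 6 genes for the daily regimen, 4 above and 2 below. Under TMM scaling these were 8 (2 above, 6 below) and 6 (6 above, 0 below), and the calls of Tmem100 and Fbn1 were lost (adjusted p = 0.0832 for both). Without the third library of each group 1 and 0 genes passed, with 1624 and 663 at an unadjusted p under 0.05. For the weekly regimen 55, 0 and 1 passed without the mouse vehicle 1, 2 and 3 and 0, 191 and 1 without weekly 1, 2 and 3. For the daily regimen 0, 2 and 1 passed without vehicle 1, 2 and 3 and 0, 9 and 0 without daily 1, 2 and 3. By limma 0 of the 9 genes named for the weekly regimen and 0 of the 5 named for the daily regimen kept the call without each mouse in turn.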

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

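The differences between the tissues were tested as planned, and the counts without the third library of each group were chosen after the results had been seen.

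The effect of the weekly regimen differed between muscle and adipose tissue for 326 genes, and that of the daily regimen for 6, by limma on the difference within each mouse. The weekly count depends on the scaling: it was 8 under TMM scaling and 1 under quantile normalization, and the daily count was 6 and 7, with 0 genes below in both (1618 genes at an unadjusted p under 0.05 without scaling). Differences are muscle minus adipose on the log2 scale. After weekly prednisone the muscle effect lay above the adipose effect for Sec61g, a subunit of the translocon (0.79 ± 0.16, adjusted p = 0.0437), Myom3, a protein of the muscle M band (0.70 ± 0.11, 0.0312), Hsd11b1, which regenerates active glucocorticoid (0.69 ± 0.15, 0.0483), and Ldhb, a subunit of lactate dehydrogenase (0.56 ± 0.11, 0.0407). It lay below for Fbn1 (-1.48 ± 0.22, 0.0302), Thbs1 (-1.40 ± 0.16, 0.0201), Tmem100 (-1.29 ± 0.19, 0.0292) and Fndc1 (-1.27 ± 0.28, 0.0458), and for Eif4a-ps4 (-2.94, 0.0376), which is uncertain because it shares reads with its parent gene. In adipose tissue Hsd11b1 was at -0.65 and in muscle at 0.04. After daily prednisone the muscle effect lay above for Myl4 (2.94 ± 0.37, 0.0441), Spp1 (2.84 ± 0.34, 0.0441) and Tubb2b (1.27 ± 0.13, 0.0201). It lay below for Adamtsl5 (-1.07 ± 0.14, 0.0441) and mt-Atp6 (-0.82 ± 0.10, 0.0441), the latter uncertain for reads shared with nuclear copies. Of these genes Thbs1 (adjusted p = 0.0449), Myom3 (0.0449), Myl4 (0.0478), Spp1 (0.0418) and Tubb2b (0.00603) passed under TMM scaling. The others did not, with 0.0832 to 0.116 for the weekly genes, 0.0544 for Adamtsl5 and 0.113 for mt-Atp6. Under quantile normalization Thbs1 missed the threshold (0.0506), and Myom3 (0.0193), Myl4, Spp1 and Tubb2b passed. Without the third library of each group the adjusted p was 0.0892 for Eif4a-ps4, 0.294 to 0.347 for the other weekly genes and 0.343 to 0.516 for the daily genes. Over the 10 splits of the mice the real one gave 326 and 6 genes, the highest other gave 0 in both, and 1 of the 10 splits, the real one, gave as many in each, which is too few splits for a share under 0.05.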

How the results depend on the processing

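Alternatives that leave out a library of every group or adipose libraries with muscle transcripts, and the muscle covariate, were chosen after the data had been seen; the others were planned. Named genes were followed under TMM scaling, quantile normalization, both pseudocounts, and with single libraries or the third library of each group left out. List calls were followed under TMM scaling, an estimated correlation, fry and the same libraries left out. The other alternatives were run for counts of genes alone. In the settings followed, 5831 values kept their direction and side of the threshold, 1134 passed no longer and 47 passed newly. A further 95, each of a named gene, changed sign while called in neither fit, and 2, each of a list, reversed. Counts of genes are not in this tally. They are given below where they moved, which means over 1.5 times apart from the reported count. Named genes kept direction and side in 497 cases under TMM scaling and 480 under quantile normalization. They did so in 545 and 549 cases with pseudocounts of 0.1 and 5, and in 348 without the third library of each group. These cases include genes called in neither fit. The calls of named genes that were lost numbered 41 under TMM scaling and 59 under quantile normalization. With pseudocounts of 0.1 and 5 they numbered 13 and 8, and without the third library of each group 206. Of the list calls by camera 83 were kept and 13 lost under TMM scaling, 4 kept and 92 lost with an estimated correlation, 38 kept and 58 lost by fry, which tests whether the genes of a list move on balance in 1 direction, and 79 kept and 17 lost without the third library of each group, where lists called fell from 13 to 9 in muscle after weekly and from 14 to 9 in adipose tissue after daily prednisone. The depth of the libraries is unknown, so what it limits cannot be stated.

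Counts of genes that moved are given for muscle weekly against vehicle (MW, 6 as reported), muscle daily against vehicle (MD, 1674), muscle weekly against daily (MWD, 217), the same in adipose tissue (AW, 1052; AD, 1; AWD, 44) and the tissue difference of the weekly (IW, 326) and daily effect (ID, 6). A minimum log2 fold change of 1 gave MW 2, MD 75, MWD 49, AW 64, AD 0 and AWD 9, fewer by construction. TMM scaling gave MD 822, AWD 14 and IW 8, and quantile normalization MD 764, AW 674, AWD 19 and IW 1. Without a filter MW was 0, AW 306, AWD 8 and IW 24, and with a filter at 5 TPM MW was 3, AD 2, AWD 72 and ID 18. A pseudocount of 0.1 gave AD 0, IW 177 and ID 2, and one of 5 gave AD 0, IW 657 and ID 24. A block for the replicate number gave MW 0, MWD 100, AD 0 and AWD 12, and IW was 510 and ID 73 without pairing by mouse. Array weights, whose estimate did not converge in several fits, gave MW 272, MD 5166, MWD 4159, AW 7679, AD 2820 and AWD 3941. These weights were highest for the third library in every group, from 1.29 for muscle vehicle 3 to 19.53 for muscle daily 3. The counts with array weights thus lean on the libraries in doubt. Transcripts in place of genes gave MWD 80, AW 31 and AWD 3, both tissues in 1 fit AW 3020, AD 12 and AWD 325, and only the groups compared MW 10, MWD 78, AW 485, AD 3 and AWD 16. Except for the stricter threshold, the cause was not tested, for these counts or those that follow.

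With 2 libraries per group most counts fell, but not all: without the second library AW was 1319, and it was 1 without the third. Without the first library of each group MD was 935, MWD 38, AW 135, AD 7, AWD 6, IW 1 and ID 1. Without the second MW was 0, MD 584, MWD 83, AWD 1, IW 0 and ID 2. Without the third MW was 0, MD 8, MWD 10, AW 1, AD 0, AWD 0, IW 1 and ID 0. Without adipose weekly 2, weekly 3 and daily 2 AW was 2145, AD 11 and AWD 2. Without adipose weekly 1 and daily 2, a set left out in error and kept because its counts had been seen, AD was 16 and AWD 101. The muscle covariate gave AW 4130 and AWD 1794. With each library left out in turn the counts were 0 to 1 for MW, 532 to 1668 for MD, 37 to 282 for MWD, 64 to 1240 for AW, 0 to 14 for AD, 2 to 33 for AWD, 0 to 191 for IW and 0 to 9 for ID. Among these the counts over 1.5 times apart from the reported ones reached 961 for MD, 125 for MWD, 405 for AW and 24 for AWD, and 2 for ID. By limma the counts of 0 stand beside 1891 (MW), 1305 (AD), 2242 (AWD), 3294 (IW) and 1618 (ID) genes at an unadjusted p under 0.05.

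Genes called for both regimens were, under TMM scaling, 2 higher and 1 lower in muscle, and without the third library 0 higher and 0 lower in muscle and 0 higher in adipose tissue. At an unadjusted p they were 102 higher and 1140 lower in muscle and 495 higher and 421 lower in adipose tissue. In adipose tissue after daily prednisone ribosomal proteins reversed without vehicle 1 (adjusted p = 0.888, from 3.78e-08 over all single libraries left out) and fast fibre genes without daily 2 (adjusted p = 0.430, from 4.60e-05), and the cause was not tested.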

Other observations

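In this part, the tests of the third library, of the regeneration genes in muscle and of the scaling in adipose tissue were chosen after the results had been seen; the tests of other splits and of skeletal muscle in the adipose samples were set before.

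Some lists held called members without passing as a whole in adipose tissue after weekly prednisone, and their genes are named after their values were seen. Of 21 genes of the cholesterol list 5 rose (adjusted p of the list = 0.106). Of 20 lipogenesis genes 4 rose and 1 fell (adjusted p of the list = 0.135), with Acly, which makes cytosolic acetyl-CoA, higher by 0.56 ± 0.07. In the unfolded protein response 5 rose and 1 fell (adjusted p of the list = 0.135). Under TMM scaling Acly was higher by 0.44.

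In muscle after daily prednisone, genes of insulin and growth factor signalling changed both ways: of 22 genes 1 rose and 6 fell (adjusted p of the list = 0.12), again named after their values were seen. Igf2, a growth factor active in muscle differentiation, rose by 1.37 ± 0.18, while Irs1, an adaptor of the insulin receptor, fell by 0.79 ± 0.17, Igfbp5, a binding protein of insulin-like growth factors, by 0.74 ± 0.10 and Akt2, a kinase of insulin signalling, by 0.31 ± 0.05. Of 6 markers of neutrophils and mast cells 3 fell (adjusted p of the list = 0.0679), among them the mast cell proteases Mcpt4 by 0.70 ± 0.11 and Tpsb2 by 0.76 ± 0.11. Of 19 clock genes 4 fell (adjusted p of the list = 0.157), with Usp2 lower by 0.44 ± 0.05.

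Among the genes with the highest mean TPM, the third library was most often the middle one in 6 of 6 groups. This has a chance of 0.00412 for groups that are independent and of 0.111 if the tissues of a mouse go together. On the first principal component, the direction in which libraries of a tissue differed most, it lay outside the others in muscle vehicle and weekly. There it stood at -8.9 (others -17.3 and -14.2) and -0.77 (others -9.6 and -5.1), and in the other groups it lay between. That the reads of the first and second libraries were joined by computer is argued against, since of the genes at 0 in both at least 4.59% were above 0 in the third, in each group. A mix of RNA from the first and second mouse stays open: a mix of the other libraries left the smallest residual for the third library in 6 of 6 groups, but fewer immunoglobulin segments seen in the third adipose library alone, which a mix would also give, were not found in all groups, where such segments numbered 0 or 1 in any library and decide nothing. A chance order of separate mice also stays open. Triples of libraries from different groups gave lowest residual ratios of 0.197 to 0.408 in muscle and 0.209 to 0.609 in adipose tissue. The ratio of the third library was below this range in daily muscle (0.14), the group behind the 1674 genes, and above it in weekly muscle (0.518). It lay within the range in vehicle muscle (0.293) and in adipose tissue (0.216 to 0.361). This comparison cannot decide on chance, since the triples also hold treatment differences and only the lowest ratio of each was kept. With unchanged simulated groups, mixing the libraries in this way let a median of 751 to 936 genes pass. With 3 separate libraries the median was 0 by limma, and 5.05% to 5.2% of genes had an unadjusted p under 0.05. The observed counts lay below those of such a mix in muscle after weekly prednisone (6 against 751) and between the regimens (217 against 798.5). They also lay below it in adipose tissue after daily prednisone (1 against 936) and between the regimens (44 against 892). They lay above it in muscle after daily (1674 against 765) and adipose tissue after weekly prednisone (1052 against 891.5). These counts cannot decide on a mix, since the simulated mix was not matched to the residual ratios of the real libraries.

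Embryonic and regeneration genes were higher in muscle after daily prednisone. Scaling as the cause is argued against, since 7 of the 8 genes called higher stayed called under TMM scaling and 7 of the 8 under quantile scaling. A larger piece of slow muscle in the dissection is argued against, since the mature slow genes Myl3, Myl2 and Myh7 changed by at most 0.25 where Tnni1 rose by 2.87, and a change in 1 mouse alone is argued against, since the median of all 14 genes of the list, called or not, was 0.87 with all daily libraries and 0.79, 0.99 and 0.85 without daily 1, 2 and 3. Regeneration in daily-treated muscle, which the groups of the design would give, is therefore a hypothesis that these data suggest but that no histology here tests, and loss of innervation, which raises Myog and Chrna1 as well, stays open as untested. All these values share the doubt about the third library.

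More genes were higher than lower in adipose tissue after weekly prednisone (76.9% of those called). Skeletal muscle in the samples is argued against as the cause, since the added muscle share would bring 0.463% of the observed rise of the median gene, and over 0.5 of the rise for 7 of 809 genes. The scaling of the values may account for the excess: under TMM scaling 47.8% of called genes were higher. A shift in the cell types of the samples, with more stroma and mesothelium and less of the fat cell, stays open, as does a true excess of higher genes, because TPM within a library cannot tell a rise of many genes from a fall of a few abundant ones.

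Other splits of the 6 libraries into groups of 3 were counted for each comparison, 10 in number, which is too few for a share under 0.05. In muscle the real split gave 6 (weekly), 1674 (daily) and 217 genes (weekly against daily), the highest other split gave 2, 1 and 1, and 1 split, the real one, gave as many in each. In adipose tissue after weekly prednisone the real split gave 1052 genes, the highest other 2, and 1 split gave as many. After daily prednisone the real split gave 1, the highest other 3, and 5 splits gave as many. For weekly against daily prednisone the real split gave 44, the highest other 47, and 2 splits gave as many.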
